A study of Mus musculus with 4 samples.

How the data were processed

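The 4 samples were stomach tissue of FVB mice aged 1 year, 2 labelled Hdc+/+ and 2 labelled Hdc-/-. The tissue was washed and minced, and total RNA was extracted with Trizol, per the labels' protocols. Biotin-labelled cDNA made from 5.5 ug of total RNA was hybridised to Affymetrix arrays, per the labels' protocols. The values used are log2 probe set values deposited by the authors, normalized across the arrays with RMA, per the submitters' processing notes, which also name oligo and Affymetrix Power Tools without versions or roles. The level at which probes were summarised, any filter and the genome build of the array annotation are not given in the sources used here, so no coordinates are printed. The values ran from 0.384 to 13.3 and the array medians from 4.05 to 4.15, as log2 values do, and no scale was changed before the tests.

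The table held 41345 probe sets, of which 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none. Of those with 1 symbol, 23328 matched the gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols needed an update. That table was used for names and for which genes neighbour each other. Probe sets with 1 gene symbol were kept, and where a gene had several, as 1082 genes did, the probe set with the highest mean over all 4 arrays stood for it, which left 22180 genes. Signal over background could not be set per probe set, since no background values were used here, and no dim gene was left out of the tests.

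Knockout-labelled arrays were compared with wild-type-labelled arrays by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes and no covariate, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The fit had 2 residual and 3.62 prior degrees of freedom. Every adjusted p for a gene or a list is from limma. An exact two-sided permutation test of 1 gene in this design cannot give a p below 0.333. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 33 lists that had at least 3 measured genes and are not the sex-linked check. The same lists were run with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance. All differences are knockout-labelled minus wild-type-labelled, an error given as SE is the moderated standard error, and each group had n = 2.

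The comparison, the tests, their alternatives, the gene lists and the rule for naming genes were set before the data were examined. The rule names Hdc, then up to 10 genes per direction with the largest log2 fold change among those past the threshold without overlap between groups. Where fewer passed, names were filled up to 5 per direction with the largest changes among genes at an unadjusted p under 0.05 without overlap, which are said not to pass, and predicted genes were passed over. For each list the rule names up to 4 passing members with the largest change, or the 2 with the smallest p. Further list members, named because they passed when adjusted over the list alone, were chosen after their values were seen. The hepatocyte list, the small nucleolar RNA class and a block that crosses the replicate numbers were also chosen after seeing the data.

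The fit and the list test were tried on simulated data with the same 22180 genes and variances drawn from the fitted prior. Each simulated gene varied independently of the others. With 50 genes changed at each size, limma called 2 (4.00%) at a log2 change of 1, 41 (82.0%) at 2 and 50 (100%) at 4 and at 6, and 3 unchanged genes were called. Of 10 lists of 20 genes shifted by 0.5 on the log2 scale, camera called 10 with the preset correlation and 0 with an estimated one. Of 30 unshifted lists it called 0 in either case. Real lists had estimated correlations from -0.105 (chief cell) to 0.606 (intestinal epithelium). The simulation therefore cannot show how often camera with the preset correlation calls unshifted lists of correlated genes.

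The alternatives left out the dimmest 25% or 50% of genes, averaged the probe sets of a gene, normalized the deposited values again by quantiles or cyclic loess or centred the arrays, used a trended and robust prior, took the replicate number as a block, left out each array in turn, tested every probe set, and used an unadjusted p with a log2 fold change of at least 1. When an array was left out, the lone array of its group was taken to vary like those of the other group. Probe sets with several symbols or none were tested only among all probe sets, where limma called 0 of these 17824 probe sets in either direction, against 797 higher and 761 lower at an unadjusted p under 0.05.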

Results

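The series compared gene expression in stomach tissue of FVB mice aged 1 year that carry or lack a functional Hdc gene. Hdc encodes histidine decarboxylase, the enzyme that makes histamine. Total RNA was measured on 4 Affymetrix arrays, 2 labelled Hdc+/+ and 2 labelled Hdc-/-, called wild-type-labelled and knockout-labelled arrays here. The sample titles call the arrays of a genotype biological replicates, and nothing further states that they came from separate animals, so p-values measure the spread between these samples. Each array gave values for 41345 probe sets on the log2 scale, with medians of 4.15 and 4.05 on wild-type-labelled arrays 1 and 2 and of 4.06 and 4.14 on knockout-labelled arrays 1 and 2. After naming, 22180 genes were compared, and the small number of arrays limits the precision of every value. The first principal component held 58.5% of the variance and placed the wild-type-labelled arrays at -11.32 and -51.29 and the knockout-labelled arrays at 33.75 and 28.86. Xist, the RNA of the inactive X chromosome, read between 8.45 and 9.01 on all 4 arrays, and the Y-linked gene Kdm5d read between 2.02 and 2.69, so the sex-linked genes gave no sign of a difference in sex between the arrays.

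The targeted gene was examined first, because it can check the genotype labels. Hdc read 3.99 and 3.82 on the wild-type-labelled arrays and 3.77 and 4.06 on the knockout-labelled arrays. The difference was 0.01 on the log2 scale (SE 0.19, n = 2 per group, limma adjusted p = 0.997). The signal lay between the 32.0th and the 36.8th percentile of genes on every array and below each array's gene median, which ran from 4.56 to 4.60. Whether the probes lie in the deleted part of the gene is not given in the sources used here, so Hdc did not check the labels, and every direction below rests on the labels alone.

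H2-Ea, which encodes the alpha chain of the class II histocompatibility molecule E, rose on the knockout-labelled arrays. It read 3.36 and 3.02 on the wild-type-labelled arrays and 7.65 and 7.47 on the knockout-labelled arrays, a log2 difference of 4.37 (SE 0.19, n = 2 per group) or 20.6-fold, with a limma adjusted p of 0.0217. It was the 1 gene of the 22180 that passed in the higher direction, and limma called 0 genes lower. At an unadjusted p under 0.05, 816 genes were higher and 1081 lower, against 1109 in total that chance would give. The 2 groups did not overlap for 4765 higher and 3912 lower genes, and chance gives such a separation in 33.3% of genes. With a trended and robust prior limma called 3 genes higher and 2 lower. The H2-Ea difference was 4.54 without wild-type-labelled array 1, where the call stood. It was 4.20 without wild-type-labelled array 2, 4.28 without knockout-labelled array 1 and 4.45 without knockout-labelled array 2, where the call was lost. Each of these fits had 1 residual degree of freedom, so a lost call there does not show that H2-Ea rests on 1 array. The call was also lost when every probe set was tested, where limma called 0 in either direction.

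The next largest differences did not pass the test over all genes. On the higher side, Cym, the gene of the milk-clotting protease chymosin, differed by 3.08 on the log2 scale (SE 0.51, adjusted p = 0.279), Gbp2b, a guanylate-binding protein gene, by 2.66 (SE 0.35, adjusted p = 0.247), Scgb2b7 by 2.67 (SE 0.92) and Cdcp3 by 2.43 (SE 0.49). The Scgb2b7 difference followed knockout-labelled array 1, being 1.17 without that array and 4.17 without knockout-labelled array 2. On the lower side stood transcripts that are abundant in liver or intestine. Alb, the gene of serum albumin, read 11.17 and 12.48 on the wild-type-labelled arrays and 4.90 and 4.71 on the knockout-labelled arrays, a log2 difference of -7.02 (SE 0.42, adjusted p = 0.0611). Serpina1c, of the alpha-1 antitrypsin family, differed by -7.61 (SE 0.56, adjusted p = 0.0611), Mup3, a major urinary protein gene, by -5.60 (SE 0.42, adjusted p = 0.0611), Pzp by -5.49 (SE 0.69, adjusted p = 0.247) and the intestinal phosphatase gene Akp3 by -5.85 (SE 1.36, adjusted p = 0.384). Without wild-type-labelled array 1 the differences were -7.68 (Alb), -8.5 (Serpina1c), -6.26 (Mup3), -6.6 (Pzp) and -8.09 (Akp3). Without wild-type-labelled array 2 they were smaller, at -6.36 (Alb), -6.71 (Serpina1c), -4.95 (Mup3), -4.38 (Pzp) and -3.61 (Akp3). Serpina1c and Mup3 belong to families of closely similar genes, so their signals could not be assigned to one member with certainty.

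**Figure D1:**
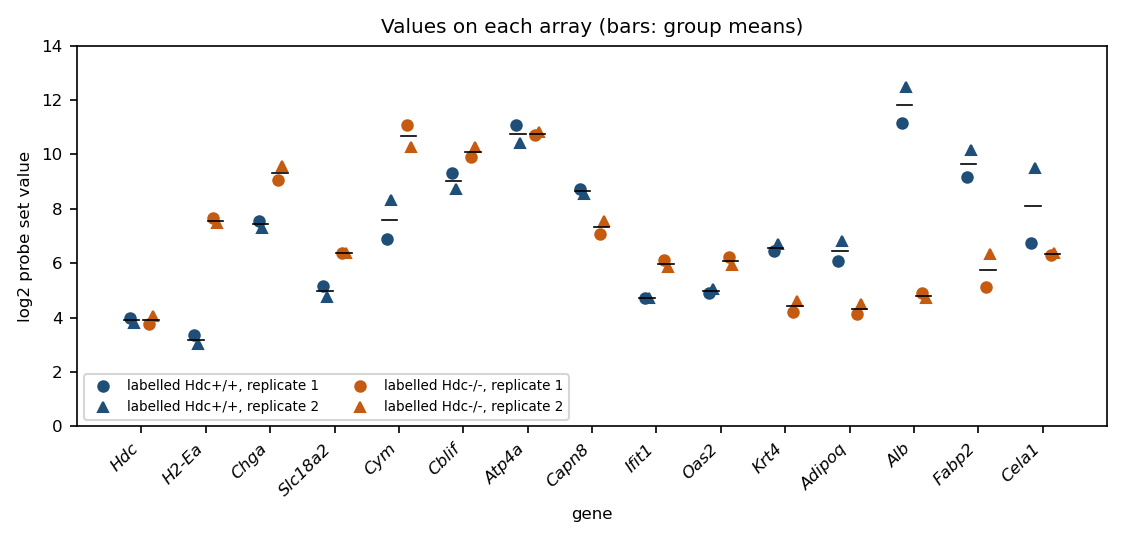
Log2 probe set values (vertical axis) of 15 genes (horizontal axis) on each of the 4 arrays, with colour for the labelled genotype, symbol shape for the replicate number and black bars at group means. Hdc lies near 4 on all 4 arrays, H2-Ea is near 3 on the wild-type-labelled and above 7 on the knockout-labelled arrays, and Alb is above 11 on the wild-type-labelled and below 5 on the knockout-labelled arrays.

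Fixed gene lists were compared with all other genes by the camera test with a preset correlation, and 16 of the 33 lists tested passed. With a correlation estimated from the data, 0 lists passed, and by the directional p of the self-contained fry test 0 passed as well. The fry p for movement in either direction was not adjusted or used for calls, and it ran as low as 0.000168 (immediate-early list). With the dimmer 50% of genes left out 9 lists passed, and the T and NK cell, class II, proliferation, pyloric antrum, endothelial, pancreatic and oxidative phosphorylation calls were lost. No list member passed the test over all genes, so counts of passing members below are adjusted over the list alone.

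Among gastric epithelial cell types, the chief cell list was shifted upward and the surface pit cell list downward on the knockout-labelled arrays, with 3 of 10 and 2 of 14 members passing when adjusted over the list alone. The chief cell list of 10 measured genes had a median log2 difference of 0.40 (camera adjusted p = 0.0119; adjusted p = 0.502 with an estimated correlation). Of the 3 chief cell members adjusted over the list alone, Cym and Cblif, the gene of gastric intrinsic factor (1.07, SE 0.25), were higher, and the protease gene Ctsc (-1.14) was lower. The pit cell list of 14 genes had a median of -0.14 (adjusted p = 0.0132; adjusted p = 0.593 with an estimated correlation). Adjusted over the list alone, 2 of its members were lower, the stomach calpain gene Capn8 (-1.32, SE 0.22) and the mucin-like gene Mucl3 (-1.23, SE 0.28). Mucl3 lies within 2 Mb of H2-Ea in the gene table of assembly GRCm38.p6. The chief cell call was lost without knockout-labelled array 2 (adjusted p = 0.0588), and the pit cell call without wild-type-labelled array 1 (adjusted p = 0.0753) and without knockout-labelled array 1 (median -0.09, adjusted p = 0.172), its median being -0.22 without knockout-labelled array 2. The chief cell median was 1.07 with the dimmer 50% of genes left out. On the same contrast, markers of liver lay lower, with a hepatocyte list median of -3.14.

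The parietal cell and acid secretion list, the epithelial group that histamine stimulates through its H2 receptor, did not pass. Its 22 genes had a median of 0.12 (adjusted p = 0.0990), with 0 members passing over the list alone by limma and 4 higher and 0 lower at an unadjusted p under 0.05. The members with the smallest p were the chloride transporter gene Slc26a7 (0.96, SE 0.31) and the nuclear receptor gene Esrrg (0.55, SE 0.20). Chosen after their values were seen, the proton pump genes Atp4a and Atp4b differed by 0.01 (SE 0.26) and 0.10 (SE 0.22). The parietal median was 0.34 without wild-type-labelled array 1 and 0.05 without wild-type-labelled array 2. Around gene means the list read 0.06 on wild-type-labelled array 1 and -0.23 on array 2. The hepatocyte and pancreatic lists read highest on that array 2 (2.73 and 1.91). The list of mucous neck cells and pyloric-type metaplasia, with 17 genes, did not pass either (median 0.09, adjusted p = 0.406). Its members with the smallest p were the transcription factor gene Sox9 (1.65, SE 0.38) and Wfdc2 (0.57, SE 0.19). Its direction depended on single arrays, since its median was -0.17 without wild-type-labelled array 1 and -0.31 without knockout-labelled array 1, and it passed upward without wild-type-labelled array 2 (0.36, adjusted p = 0.00405) and without knockout-labelled array 2 (0.44, adjusted p = 0.00215).

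A pair of genes in the endocrine and enterochromaffin-like cell list read higher on the knockout-labelled arrays. Enterochromaffin-like cells store gastric histamine, but the list also covers other endocrine cells, so the pair does not single out 1 cell type. Chga, the gene of the granule protein chromogranin A, read 7.54 and 7.30 on the wild-type-labelled arrays and 9.05 and 9.58 on the knockout-labelled arrays, a log2 difference of 1.89 (SE 0.23) or 3.71-fold. Slc18a2, which encodes the vesicular monoamine transporter that loads histamine into granules, read 5.15 and 4.77 against 6.38 on both knockout-labelled arrays, a log2 difference of 1.42 (SE 0.19) or 2.68-fold. Both passed when adjusted over the list alone, as 2 higher and 0 lower among the 24 genes of the endocrine list, and neither passed over all genes. The list as a whole had a median of 0.05 and did not pass (adjusted p = 0.0584), although it did without wild-type-labelled array 2 (median 0.13, adjusted p = 0.0377). In the histamine pathway list of 13 genes, Slc18a2 was higher and Maob, the gene of monoamine oxidase B, lower (-1.87, SE 0.32), both adjusted over the list alone. Maob read 6.70 and 7.62 on the wild-type-labelled arrays and 5.28 and 5.30 on the knockout-labelled arrays. Its difference was -2.33 without wild-type-labelled array 1 and -1.41 without wild-type-labelled array 2. Like the hepatocyte list medians (0.44 and 2.73 around gene means), Maob was highest on wild-type-labelled array 2. Whether tissue of other organs gave the Maob difference was not tested. The histamine pathway list did not pass (adjusted p = 0.310). Its median of 0.01 and mean of -0.30 differed in sign, the test following the mean. The median was -0.49 with the dimmer 50% of genes left out. On the same arrays the intestinal list had a median of -1.23.

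The list of interferon-induced genes was shifted upward on the knockout-labelled arrays, with 6 of 20 members passing when adjusted over the list alone. The 20 genes had a median log2 difference of 0.48, or 1.40-fold (camera adjusted p = 1.18e-06; adjusted p = 0.502 with an estimated correlation). The 6 were all higher, among them Ifit1 (1.27, SE 0.18) and Oas2 (1.11, SE 0.18), which encode antiviral proteins. The list's camera call stood with each array left out in turn. The T and NK cell list of 19 genes was also shifted upward (median 0.23, adjusted p = 0.00471; adjusted p = 0.502 with an estimated correlation), and 0 members passed over the list alone by limma against 4 higher and 0 lower at an unadjusted p under 0.05. Its members with the smallest p were the checkpoint receptor gene Ctla4 (0.58, SE 0.17) and the T cell receptor subunit gene Cd3e (0.83, SE 0.27). The class II antigen presentation list of 12 genes, which does not hold H2-Ea, had a median of 0.16 (adjusted p = 0.0457; adjusted p = 0.502 with an estimated correlation), and 1 member, H2-Eb1, a neighbour of H2-Ea that encodes its partner chain, was higher over the list alone (1.20, SE 0.24). H2-Ob had the next smallest p (0.48, SE 0.23). This call was lost with any 1 array left out, with adjusted p from 0.0588 to 0.146. In the same contrast the hepatocyte list median was -3.14 and the squamous list median -0.52.

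Other immune lists did not pass. The macrophage and monocyte list (20 genes, median 0.06, adjusted p = 0.202) held 1 member that was higher when adjusted over the list alone, the adaptor gene Tyrobp (0.85, SE 0.16), and Adgre1, a macrophage surface marker gene, read 0.66 higher (SE 0.16). The list passed without wild-type-labelled array 2 (median 0.35, adjusted p = 0.00321), and its median was -0.04 without wild-type-labelled array 1. The cytokine and chemokine list (25 genes, median 0.06, adjusted p = 0.260) held 1 member that passed over the list alone, the chemokine gene Ccl8 (2.11, SE 0.32). Cxcl13, a chemokine that attracts B cells, read -1.65 (SE 0.56). The cytokine median was 0.11 without wild-type-labelled array 1 and 0.03 without wild-type-labelled array 2. The neutrophil and immature myeloid list (19 genes, median -0.06, adjusted p = 0.753) had a mean of 0.01, opposite in sign to its median, and Ltf and Retnlg read 1.15 (SE 0.25) and 1.58 (SE 0.38). The mast cell list (16 genes, median 0.26, adjusted p = 0.260) followed knockout-labelled array 1. Its median was -0.06 without that array and 0.74 without knockout-labelled array 2, where it passed (adjusted p = 1.21e-05), and Kit and Mcpt9 read 0.74 (SE 0.28) and -0.66 (SE 0.16). In the B and plasma cell list (14 genes, median 0.04, adjusted p = 0.632), Pou2af1 read 0.45 (SE 0.16) and Ms4a1 -0.92 (SE 0.37).

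The squamous epithelial and adipocyte lists were shifted downward on the knockout-labelled arrays, with 10 of 26 and 3 of 14 members passing when adjusted over the list alone, and the smooth muscle and endothelial lists were shifted downward by less. Genes of stratified squamous epithelium, which lines the mouse forestomach, had a median log2 difference of -0.52 over 26 genes (camera adjusted p = 4.81e-10; adjusted p = 0.502 with an estimated correlation). The 10 squamous members were all lower, including the keratin gene Krt4 (-2.15, SE 0.21) and the filaggrin gene Flg (-1.35, SE 0.20). The adipocyte list of 14 genes had a median of -0.49 (adjusted p = 2.76e-06; adjusted p = 0.502 with an estimated correlation), and its 3 passing members were lower, Adipoq, the adiponectin gene (-2.11, SE 0.29), the lipase gene Lpl (-1.5, SE 0.25) and Fabp4 (-2.88, SE 0.67). Both calls stood with each array left out in turn, with a squamous median of -0.33 without knockout-labelled array 1. The smooth muscle list (14 genes, median -0.24, adjusted p = 0.00432; adjusted p = 0.574 with an estimated correlation) included Cnn1 (-0.50, SE 0.17) and Actg2 (-0.49, SE 0.20), and its call was lost without wild-type-labelled array 2 (median -0.11, adjusted p = 0.188), its median being -0.15 without knockout-labelled array 2. The endothelial list (14 genes, median -0.16, adjusted p = 0.0213; adjusted p = 0.502 with an estimated correlation) included Emcn (-0.63, SE 0.18) and Tek (-0.55, SE 0.19), and its call was lost without wild-type-labelled array 2 and without either knockout-labelled array (adjusted p from 0.0588 to 0.226), its median being -0.24 without wild-type-labelled array 1. In both lists limma passed 0 members over the list alone, against 1 lower in the smooth muscle list and 2 lower in the endothelial list at an unadjusted p under 0.05. The fibroblast and matrix list (20 genes) did not pass (adjusted p = 0.148), with a median of 0.03 and a mean of -0.16 that differed in sign, while Lum (-1.23, SE 0.21), Sparc (-0.77, SE 0.16) and Dcn (-0.82, SE 0.19) were lower over the list alone.

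Lists of organs that adjoin the stomach were also shifted downward on the knockout-labelled arrays, and they varied between the wild-type-labelled arrays. The intestinal epithelium list of 23 genes had a median of -1.23 (camera adjusted p = 5.48e-08; adjusted p = 0.574 with an estimated correlation). Over the list alone 4 members were lower, the fatty acid binding protein genes Fabp2 (-3.92, SE 0.50) and Fabp1 (-3.91, SE 0.60), Dpp4 (-1.83, SE 0.26) and Krt20 (-1.29, SE 0.22). The pancreatic acinar list of 17 genes had a median of -1.24 (adjusted p = 0.0110; adjusted p = 0.609 with an estimated correlation), with 0 members passing over the list alone by limma and 0 at an unadjusted p under 0.05. Cela1, an elastase gene, read 6.73 and 9.51 on the wild-type-labelled arrays and 6.29 and 6.39 on the knockout-labelled arrays. Its difference was -3.17 without wild-type-labelled array 1. The colipase gene Clps read 0.45 higher (SE 0.23) on the knockout-labelled arrays. Without wild-type-labelled array 2 the pancreatic median was 0.03 (adjusted p = 0.188) and the intestinal median -0.31, the latter still passing. Without wild-type-labelled array 1 these medians were -2.45 and -1.86. The pancreatic call was also lost without knockout-labelled array 1 (adjusted p = 0.105) or 2 (adjusted p = 0.0757). A hepatocyte list of 34 measured genes, added after Alb was seen, had a median of -3.14, with 30 members lower and 0 higher when adjusted over the list alone (camera p = 2.26e-38; p = 0.0921 with an estimated correlation). Its median was -1.93 without wild-type-labelled array 2.

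**Figure D2:**
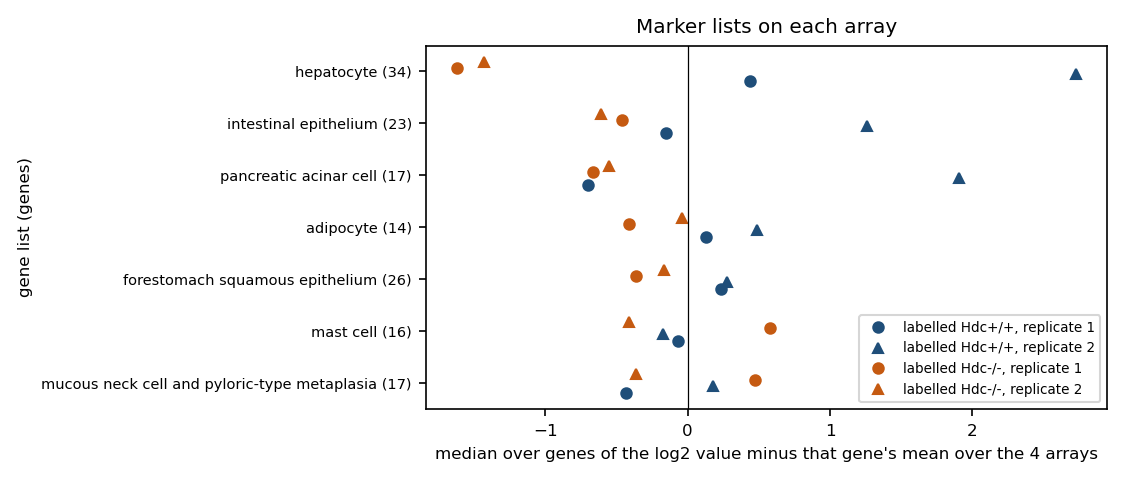
Median over the genes of a list of the log2 value minus that gene's mean over the 4 arrays (horizontal axis), for 7 marker lists (vertical axis, number of genes in brackets), with colour for the labelled genotype and symbol shape for the replicate number. The hepatocyte median is 0.44 and 2.73 on the wild-type-labelled arrays and -1.62 and -1.43 on the knockout-labelled arrays, and the pancreatic median is 1.91 on wild-type-labelled array 2 and between -0.70 and -0.55 on the other arrays.

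Growth and cell state lists moved by small amounts, while the hepatocyte list had a median of -3.14 on the same contrast. The proliferation list of 25 genes had a median of 0.20 (camera adjusted p = 0.0399; adjusted p = 0.661 with an estimated correlation), and limma passed 0 members over the list alone and 0 at an unadjusted p under 0.05. Aurka and Mcm2, a mitotic kinase gene and a replication helicase gene, read 0.35 (SE 0.16) and 0.36 (SE 0.18). The median was -0.001 without knockout-labelled array 1, and the call was also lost without wild-type-labelled array 1 (adjusted p = 0.0614) or 2 (adjusted p = 0.144), while the median was 0.33 without knockout-labelled array 2. The immediate-early list was shifted downward (16 genes, median -0.22, adjusted p = 0.0139; adjusted p = 0.502 with an estimated correlation), with Fos at -0.82 (SE 0.17) and Ier3, another neighbour of H2-Ea within 2 Mb, at 0.59 (SE 0.18). That call was lost without wild-type-labelled array 1 (adjusted p = 0.101) or knockout-labelled array 1 (median -0.05, adjusted p = 0.0858), and the median was -0.13 without knockout-labelled array 2. The cytosolic ribosomal protein list was shifted upward (31 genes, median 0.21, adjusted p = 0.0102; adjusted p = 0.661 with an estimated correlation), although the members with the smallest p were Rpl30 (-0.76, SE 0.25) and Rps16 (-0.46, SE 0.16). Medians of small nucleolar RNAs, examined after the data were seen, were 7.75 and 7.18 on the wild-type-labelled arrays and 7.98 and 8.50 on the knockout-labelled arrays. The ribosomal call was lost without wild-type-labelled array 2 (adjusted p = 0.163) or knockout-labelled array 2 (median 0.12, adjusted p = 0.431), and the median was 0.34 without knockout-labelled array 1. The nuclear oxidative phosphorylation list was shifted upward (32 genes, median 0.13, adjusted p = 0.0277; adjusted p = 0.661 with an estimated correlation), with Cox4i1 at 0.44 (SE 0.18) and Cyc1 at 0.37 (SE 0.16), and the call was lost without wild-type-labelled array 2 (median 0.07, adjusted p = 0.292) or knockout-labelled array 1 (adjusted p = 0.194). The pyloric antrum list was shifted downward (7 genes, median -0.29, adjusted p = 0.0422; adjusted p = 0.502 with an estimated correlation), with Onecut2 at -0.71 (SE 0.22) and Nkx6-3 at -0.55 (SE 0.30). It passed with 1 of the 4 arrays left out, knockout-labelled array 2, and not with any of the other 3 left out (adjusted p from 0.0576 to 0.194), with a median of -0.14 without knockout-labelled array 1. In these last 4 lists limma passed 0 members over the list alone. At an unadjusted p under 0.05 the immediate-early list had 1 higher and 4 lower members, the ribosomal list 2 and 2, the oxidative phosphorylation list 0 and 0 and the antrum list 0 and 1.

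The remaining lists did not pass. The regenerating protein and EGF receptor ligand list (13 genes, median -0.20, adjusted p = 0.192) passed downward without wild-type-labelled array 1 (adjusted p = 0.00776) and had a median of 0.01 without wild-type-labelled array 2, and Reg2 and Epgn read 0.56 (SE 0.16) and -0.45 (SE 0.20). The endoplasmic reticulum stress list (18 genes, median 0.06, adjusted p = 0.219) had Xbp1 at 0.41 (SE 0.17) and Hyou1 at 0.41 (SE 0.18). Its median was 0.16 without knockout-labelled array 2 and 0.03 without knockout-labelled array 1. The glutathione and oxidant defence list (19 genes, median 0.05, adjusted p = 0.408) held 1 member that was lower over the list alone, Gstm3 (-1.57, SE 0.22), and Duox2, an epithelial hydrogen peroxide source, read 1.91 (SE 0.56), a difference of 1.00 without knockout-labelled array 1. The cholesterol synthesis list had a median of -0.02 over 17 genes (adjusted p = 0.538), with Mvd at 0.43 (SE 0.16) and Hmgcs1 at -0.49 (SE 0.25). The circadian clock list had a median of 0.02 and a mean of -0.001 over 15 genes (adjusted p = 0.731), with Nfil3 at 0.49 (SE 0.17) and Npas2 at -0.62 (SE 0.23). The skeletal muscle list had a median of 0.12 over 15 genes (adjusted p = 0.146), with Myh1 at 0.71 (SE 0.16) and Mylpf at 0.62 (SE 0.33). The enteric neuron and glia list had a median of -0.02 over 15 genes (adjusted p = 0.714), with Ret at 0.83 (SE 0.23) and Stmn2 at -0.46 (SE 0.17). The red blood cell list had 2 measured genes, Slc4a1 (-0.16, SE 0.21) and Epb42 (0.06, SE 0.17), too few for the list test.

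**Figure D3:**
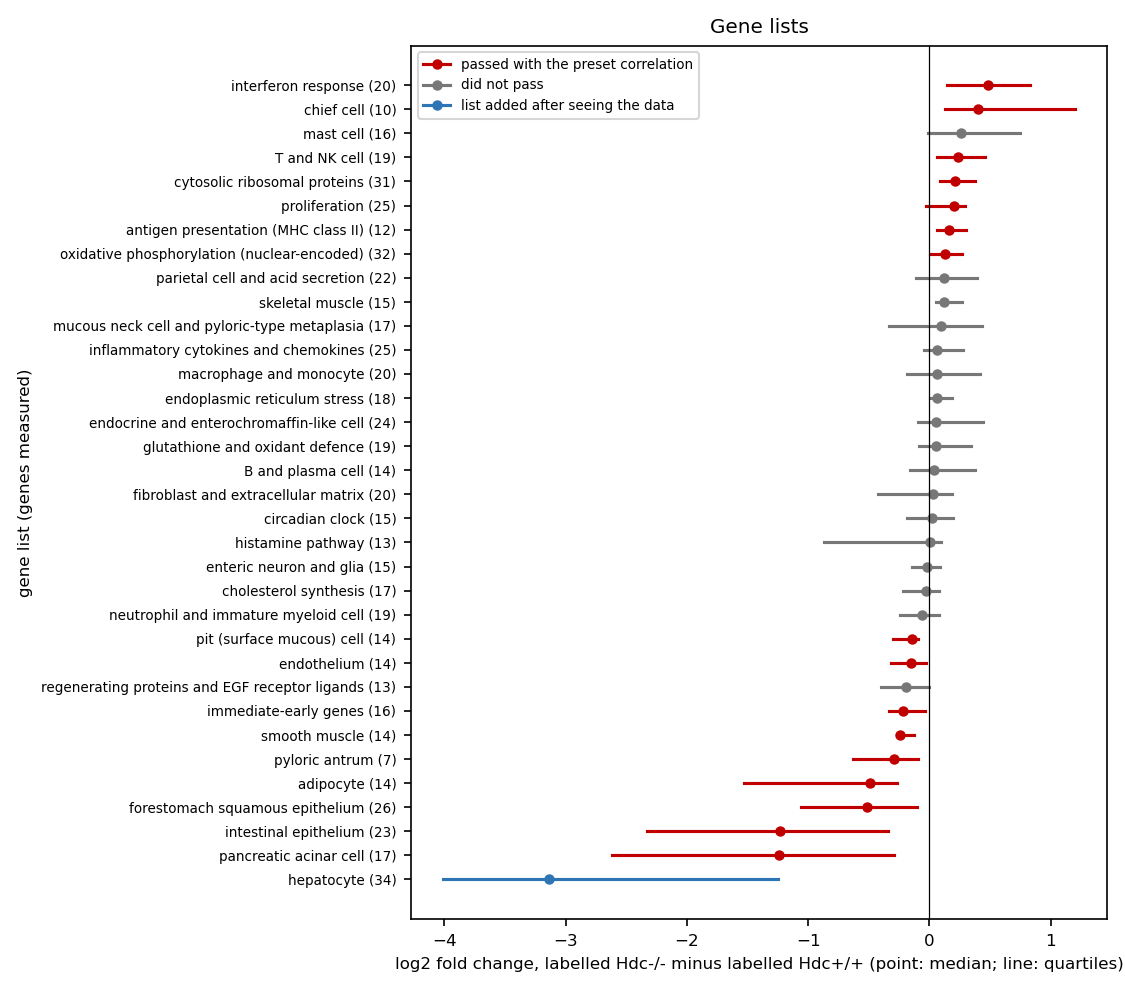
Log2 fold change of the knockout-labelled over the wild-type-labelled arrays (horizontal axis) for each tested gene list (vertical axis, number of measured genes in brackets), with points at the median over the genes of a list and lines from the lower to the upper quartile. Colour separates the 16 lists that passed camera with the preset correlation, those that did not pass, and the hepatocyte list added after the data were seen, whose median of -3.14 lies farthest from 0.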

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

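The crossed replicate block was chosen after seeing the data. The H2-Ea difference stayed between 4.20 and 4.54 under the alternatives, with an adjusted p from 0.00471 to 0.0256 in those that kept all 4 arrays and 1 test per gene and did not cross the replicates. The settings changed how many genes were called, and the cause was not tested. A trended and robust prior gave 3 higher and 2 lower genes, an unadjusted p with a log2 fold change of at least 1 gave 107 and 372, and testing every probe set, which adjusts over 41345 tests, gave 0 of either. Cyclic loess changed the higher share of genes at an unadjusted p under 0.05 from 43.0% to 36.5%, the replicate block to 34.2% and leaving out wild-type-labelled array 1 to 31.4% or array 2 to 33.5%, while leaving out knockout-labelled array 2 turned the balance, with 1025 higher and 912 lower (52.9%). Deviations of same-numbered arrays correlated at -0.119 over genes. This cannot show whether same-numbered arrays shared a batch, because genes that stood apart on single arrays enter the correlation. The labels state no pairing. The replicate block gave 1 higher and 6 lower genes (Fabp2, Alb, Cyp2e1, Cdo1, Serpina1c and Mup3) and brought the parietal list past the threshold (median 0.122, adjusted p = 0.0399), and it changed no other call. The crossed block gave 0 higher and 0 lower genes. With 1 array left out, higher genes ranged from 0 to 3, lower genes from 0 to 158 and passing lists from 8 to 14.

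Of the lists, 9 passed with the dimmer 50% of genes left out, 0 with an estimated correlation and 0 by the directional p of fry. The estimated correlation also passed 0 of 10 simulated lists that were truly shifted and whose genes varied independently. The chief, pit and proliferation medians (0.399, -0.140 and 0.20) did not pass in either of these tests. The proliferation list also missed with the dimmer 50% left out (0.211) and by cyclic loess (0.167). The class II call was also lost without the dimmer 25%, by cyclic loess and with centred arrays, and the pyloric antrum call by cyclic loess and with probe sets averaged. Medians of lists that did not pass changed sign for histamine (-0.120 and -0.494 without the dimmer 25% and 50%, -0.0333 with probe sets averaged, -0.0191 by cyclic loess), cytokines (-0.221) and neutrophils (0.154), these last without the dimmer 50%, and Hdc read -0.0135 by cyclic loess. With 1 array left out, Hdc ranged from -0.139 to 0.153, and list medians from -0.139 to 0.0377 (histamine), 0.0506 to 0.336 (parietal), 0.335 to 0.592 (chief), -0.219 to -0.0853 (pit), -0.310 to 0.443 (mucous neck), 0.0858 to 0.146 (endocrine), -0.298 to 0.0110 (regenerating) and -0.00106 to 0.326 (proliferation). Among named genes, none of which passed, Kdm5d ranged from -0.108 to 0.418, Epb42 from -0.0587 to 0.179 and Slc4a1 from -0.368 to 0.0556. Near-zero medians of further lists that did not pass (B cell, fibroblast, skeletal muscle, neuron, glutathione, cholesterol and clock) also changed sign with some array left out. So did the neuron median without the dimmer 50% (0.060) and the fibroblast and clock medians by cyclic loess (-0.009 and -0.007). The other named genes kept their direction under the alternatives run but not always their size. Of 78 named genes, Kdm5d, Epb42 and Slc4a1 included, 28 moved by over 1.5 times with some array left out. Besides these and those in the report, values came to 0.509 (Cd3e), 0.252 (Hyou1), -0.464 (Rpl30), -0.207 (Xist), -1.45 (Ms4a1) and 0.731 (Clps) without wild-type-labelled array 1, and to -0.393 (Ms4a1), 0.177 (Clps), -0.853 (Cxcl13), 0.618 (Slc26a7), 0.332 (Esrrg), 0.473 (Kit), -0.465 (Onecut2) and -0.390 (Cela1) without array 2. Without knockout-labelled array 1 they came to 1.08 (Sox9), 1.00 (Retnlg), 0.765 (H2-Ob), 0.555 (Ret), 0.466 (Kit), 0.165 (Mylpf), -0.136 (Nkx6-3), -0.289 (Actg2), -0.290 (Epgn), -0.339 (Npas2) and -0.823 (Hmgcs1), and without array 2 to 0.189 (H2-Ob), 1.08 (Mylpf), -0.966 (Nkx6-3) and -0.162 (Hmgcs1). No background values were used here, so signal over background is not given; the arrays' lower quartiles of 2.82 to 2.96 lie below every Hdc value.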

Other observations

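The tests of antigen-presenting cells, of carried-over liver, of a shared source of several lists and of genotype effects on the hepatocyte, intestinal and pancreatic lists were chosen only after the result was seen, and so were the genes of this paragraph and the next. Knockout-labelled array 1 stood apart for 28 genes that read over 2 log2 units above the other 3 arrays. They included Chil4, a chitinase-like gene (11.09 against 3.46 to 3.82), the mucosal mast cell protease genes Mcpt1 (9.41 against 3.23 to 4.54) and Mcpt2 (8.37 against 4.44 to 5.21), the intelectin gene Itln1 (9.56 against 4.16 to 5.71), Pla2g4c (9.89 against 5.10 to 5.62) and the gland mucin gene Muc6 (11.94 against 8.40 to 9.30). Wild-type-labelled array 2 had 134 such genes, among them the pancreatic genes Cpa1 (10.20), Cpb1 (9.95) and Ctrb1 (10.94) and the regenerating protein gene Reg1 (10.28), none of which read above 5.25 on another array. Wild-type-labelled array 1 had 0 and knockout-labelled array 2 had 1. That gene was Kcnma1, at 12.26 against 3.96 to 4.13, but its other probe set read 4.13 on the same array, so its probe sets disagree.

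Small nucleolar RNAs, which guide modification of ribosomal RNA, read higher on the knockout-labelled arrays in 70 of 73 measured genes, with a median log2 difference of 0.61 (camera p = 5.5e-24; p = 0.208 with an estimated correlation). Their medians were 7.75 and 7.18 on the wild-type-labelled arrays and 7.98 and 8.50 on the knockout-labelled arrays, so arrays of one genotype differed as well. At an unadjusted p under 0.05, 34 were higher and 0 lower. The heat shock genes Hspa1a and Hspa1b read 1.22 and 1.26 higher on the knockout-labelled arrays, neither passed over all genes, and both lie within 2 Mb of H2-Ea.

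The H2-Ea rise came with mixed differences in its neighbourhood: within 2 Mb, 28 of 189 genes (14.81%, against 8.53% elsewhere, one-sided Fisher's exact p = 0.00312) passed an unadjusted p under 0.05, 18 higher and 10 lower, among them H2-Eb1 (1.20), H2-T10 (-2.10), H2-Q5 (1.17), Hspa1a, Hspa1b, Ier3, Mucl3 and Cfb of the hepatocyte list, while H2-Aa and H2-Ab1 differed by -0.06 and -0.10. More antigen-presenting cells in the tissue are argued against, since the class II list had a median of 0.16, quartiles of 0.0621 and 0.302 and a highest member at 1.20, all far below 4.37. H2-Ea expression differs between mouse strains, so another strain's DNA at this locus in the knockout-labelled animals is a candidate explanation. The window was centred on the gene that passed over all genes, so its place was not chosen independently of the data. The rate near H2-Ea was 1.74 times that elsewhere, above chance and below the ratio of 2 set before this test was run. Strain DNA and an effect of the genotype on this gene cannot be told apart here, because that ratio fell between the bounds set for the test and no genotype at this locus was measured.

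Genes within 20 Mb of Hdc passed an unadjusted p under 0.05 at 0.728 times the rate of genes elsewhere (24 of 382, 6.28%, against 8.63%). This gives no sign that strain DNA next to the targeted gene altered many genes there. With 382 genes in the window and 1864 genes past that p elsewhere, the test could not bear on the source of most differences. It also cannot exclude an effect on a few genes near Hdc, because the rate elsewhere also counts hepatocyte, intestinal and other marker genes. Pieces that held unequal amounts of forestomach, muscle, pancreas or fat may account for part of the other differences. Of those lists, the pancreatic one had the largest median, -1.24, which came to 0.03 without wild-type-labelled array 2. The squamous median of -0.52 lay beyond the bar of 0.5 set in advance. It lay inside the bar without wild-type-labelled array 2 (-0.40), knockout-labelled array 1 (-0.33) or knockout-labelled array 2 (-0.485). The median lay farther beyond the bar without wild-type-labelled array 1 (-0.593). So did the median of the 9 squamous genes kept with the dimmer 50% of genes left out (-1.125). An effect of the genotype on the squamous and fat tissue itself was not tested and stays open.

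Hepatocyte genes were high on both wild-type-labelled arrays, where Alb read 11.17 and 12.48 and Ttr 9.17 and 10.50, and intestinal and pancreatic genes were high on wild-type-labelled array 2. A single carried-over tissue is argued against as the source of both the hepatocyte and the pancreatic genes: given the share of their array 2 excess that hepatocyte genes kept on array 1 (lower quartile 0.177), the pancreatic genes lay a median of -1.02 from the predicted log2 value (quartiles -3.10 and -0.60), with Cpa1 at 4.11 against 7.81. An effect of the genotype on gastric cells is argued against for the pancreatic list, of which 35.3% lay higher on both wild-type-labelled arrays (16.7% by chance) and whose array 1 values lay a median of -0.03 from the knockout-labelled mean and at most 0.39 above it, against a lower quartile of 1.67 on array 2. For the hepatocyte and intestinal lists, the share of genes higher on both wild-type-labelled arrays cannot tell carried-over liver or intestine from a genotype effect. Of the hepatocyte genes, 97.1% (33 of 34, in a list chosen after Alb was seen) lay higher on both arrays, as either would give. The 60.9% of intestinal genes fell between the bounds set for the test. Hepatocyte genes lay a median of 1.79 higher on wild-type-labelled array 2 than on array 1 (quartiles 1.23 and 2.19). For intestinal genes this median was 1.14 (quartiles 0.608 and 2.24). The knockout-labelled arrays differed by medians of 0.108 and -0.004. Such a spread within 1 genotype argues against the genotype as the only source of these differences. Whether it gave part of them stays open. On the knockout-labelled arrays too, 14 of the 34 hepatocyte genes read above the gene median of 4.59, and 2 are also intestinal list members. Whether those lists share 1 source stays open as well, with intestinal genes at a median of -0.17 from the predicted value (quartiles -1.12 and 0.08).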
